A study of Mus musculus with 5 samples.

How the data were processed

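RNA from 5 libraries of mouse peritoneal lavage cells was measured by Smart-seq2 RNA sequencing: 1 from WT mice given PBS, 2 from WT mice given pristane and 2 from mice described as Irf8-deficient given pristane. The deposited table is named a count table by the authors, but its values were FPKM: they were not whole numbers, and among genes with a single annotated transcript the lowest values multiplied by transcript length gathered at 1 and 2 times one constant per library. The authors' processing notes name BWA, TopHat2 2.0.10, Cufflinks 2.2.1 and Cuffnorm without saying which step each carried out. Whether the libraries were also scaled to each other, the genome build and the annotation are not given in the sources used here. The table listed 22815 gene symbols, of which 27 had been turned into dates by a spreadsheet and were never named. Symbols were used as listed, and older ones were matched to the gene lists by hand (Emr1 for Adgre1, Irg1 for Acod1).

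Depth was estimated from the table, since no read totals were used here. For genes with 1 transcript of at least 1000 bp and values under 0.3 FPKM, the FPKM of a single fragment was read as the most frequent product of value and length. Among the products that rounded to 1 or 2 fragments, between 67.1% and 81.0% lay within 0.15 of that whole number. Some genes were listed at exactly 0 in a library while other libraries held 10 FPKM or more, so a 0 may be a failed estimate, and the text gives no fold change for a gene, or for a list made up of genes, listed at 0 throughout 1 group. Members of gene families with similar sequence, such as Ifit, Oas, Gbp, Ms4a and stefin genes, may share fragments.

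Genes were tested with limma 3.58.1 in R 4.3.3 (limma-trend) on log2(FPKM + 1), with 3 group means and all 5 libraries in a single fit. Genes with at least 1 FPKM in at least 1 library were kept, 11117 in all. Residual degrees of freedom were 2, from the pristane pairs, and prior degrees of freedom 1.99. The PBS library alone in its group was assumed to vary as the pristane libraries did. P-values were 2-sided and adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 counted as past the threshold. Log2 changes are differences of group means on the log2(FPKM + 1) scale, each with its standard error (SE). The design, fixed before the data were examined together with the gene lists, the named-gene rule and most alternatives, had foreseen counts and named limma-trend for any other unit.

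Gene lists were tested with camera from limma with a preset correlation between genes of 0.01, over the 41 of 43 lists with at least 3 tested genes and adjusted over these. Camera compares a list with all other genes. The same test with a correlation estimated per list and fry, which tests a list's own genes for a shared direction, were run beside it. With an estimated correlation 0 of 41 lists passed in each comparison. That form of the test rests on the 2 residual degrees of freedom, so hardly any list could pass it here. Its p-values therefore do not show that correlation between genes undoes a call. For mast cell markers after pristane in WT the estimated correlation was −0.089, below the preset 0.01, and the adjusted p was still 0.487. Other lists had estimates well above the preset: 0.436 for inflammatory monocytes, 0.494 for large peritoneal macrophages and 0.502 for B cells. The type I interferon list had 0.041. Where genes of a list do vary together more than the preset, its camera p-value is too small. "Adjusted over the list alone" means Benjamini-Hochberg adjustment over the tested members of 1 list. Genes named in the text were Irf8, up to 10 genes with the largest rise and fall past the threshold with a mean log2 value of at least 3 and no overlap between groups, and from each list up to 4 members with the smallest p and 2 with the highest level. Predicted genes and antigen receptor segments were not named. Genes named outside this rule, as in the part on other observations, were chosen after their values were seen. Lists share some members, such as F10 and F5 between coagulation and large peritoneal macrophage markers.

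The tests were tried on simulated data with the same groups and noise drawn from each gene's variance as adjusted by limma. In each trial 100 genes were changed by 2 on the log2 scale and 100 by 4, and 1 list was shifted. A log2 change of 2 was called in 90, 79 and 88 of 100 genes for Irf8KO against WT pristane, WT pristane against PBS and Irf8KO pristane against PBS, and 7, 14 and 10 unchanged genes were called. A list shifted by 1 on the log2 scale was recovered at 1.01, 0.98 and 0.98, and 0, 1 and 1 of the other lists were called. Each gene was drawn independently, while the estimated correlation within the real lists reached 0.979 (MHC class II). The trial therefore cannot show how often genes that vary together bring a false list call. It also gave the PBS library the spread of the other libraries, so it does not check that assumption. The adjusted variances differ less between genes than the measured ones, so the shares called may be higher than in the real data. In the real comparison of Irf8KO with WT pristane, Irf7 (log2 change −4.92) and Zbp1 (−3.68) had a limma adjusted p of 0.0541. The covariance and correlation of log2 changes in comparisons that share libraries were set beside 100 simulated draws of unchanged groups that share the same libraries.

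Alternatives changed 1 choice at a time, except the replicate block, which also left out the PBS library: scaling by median of ratios, library totals or upper quartile; no filter or a mean of at least 5 FPKM; a pseudocount of 0.1 or 5; a robust prior; a test against a log2 change of 1; leaving out each pristane library; the 4 pristane libraries alone; and the replicate number as a block. Genes above 0 in every library and a fit with no variance trend were added after the data were seen. Count-based tests were left out because the values are not counts. Leaving out the PBS library gives no value for the comparisons that need it. Python tools were pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.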

Results

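Cells recovered from the peritoneal cavity of 8-week-old mice were profiled by Smart-seq2, a method for sequencing polyadenylated RNA from little material. Pristane is a hydrocarbon oil that provokes lasting sterile inflammation in the mouse peritoneum and, in the C57BL/6 strain, bleeding into the lung air spaces. Irf8 is a transcription factor needed for the development of monocytes and dendritic cells, and Irf8-deficient mice make an excess of granulocytes. The 5 libraries fell into 3 groups: C57BL/6 (wild type, WT) mice given phosphate-buffered saline (WT PBS, n = 1), WT mice given pristane (n = 2) and mice described as Irf8-deficient given pristane (libraries labelled Irf8KO, n = 2). The labels do not say whether replicates came from separate animals, so p-values measured only the spread between these libraries. The table listed 22815 gene symbols with FPKM values (fragments scaled to transcript length and sequencing depth), and 11117 of them were tested. Summed FPKM ran from 451694 to 582696 per library, and from 9105 to 9849 genes reached 1 FPKM. The steps between the lowest listed values corresponded to about 2282000 assigned fragments in the PBS library, 4032000 and 2849000 in the WT pristane libraries and 4957000 and 3306000 in the libraries labelled Irf8KO. At these depths 1 fragment on a transcript of 1 kb was worth 0.202 to 0.438 FPKM.

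Irf8 itself was read first, as the gene named in the genotype. Irf8 stood at 32.4 FPKM in the PBS library, 63.3 and 48.7 FPKM in the WT pristane libraries and 120.5 and 59.4 FPKM in the libraries labelled Irf8KO. Between the pristane groups the log2 change was 0.60 ± 0.41 (SE) with an adjusted p of 0.471 and a 95% interval from −0.53 to 1.73 (limma), so no fall of Irf8 RNA was seen in the libraries labelled Irf8KO and a 2-fold one lay outside the interval. Without Irf8KO pristane replicate 1 the log2 change was 0.09, and without Irf8KO pristane replicate 2 it was 1.10. Values per gene do not show which exons the fragments came from, and the kind of mutant allele is not given in the sources used here. Transcripts that mark the sex of an animal differed within the WT groups. Xist, expressed from the inactive X chromosome of females, stood at 43.5 FPKM in the PBS library and 8.81 FPKM in WT pristane replicate 2, and was listed at 0 in WT pristane replicate 1. The Y-linked Eif2s3y stood at 12.9 FPKM in WT pristane replicate 1 and at 23.2 and 25.6 FPKM in the libraries labelled Irf8KO, and was listed at 0 in the other 2.

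WT pristane against WT PBS asked what the oil did to the peritoneal cells of normal mice. The resting peritoneum holds mostly large resident macrophages, B cells and some mast cells. After pristane the transcripts of all 3 of these cell types fell, and those of neutrophils, inflammatory monocytes and natural killer cells rose. Type I interferon response genes and genes of glycolysis and matrix breakdown rose as well. Of the 23 lists that passed by camera, 8 also passed by fry, those of mature neutrophils, mast cells, B cells, the type I interferon response, matrix proteases, lipid uptake, glycolysis and ribosomal proteins, and the other 15 had a fry adjusted p from 0.0549 to 0.242. In total 1183 genes passed the threshold, 576 higher and 607 lower, of which 53 and 132 were listed at 0 in every library of 1 group. The balance turned on the filter: 372 were higher and 901 lower with no filter, and 808 higher and 368 lower with a mean of at least 5 FPKM. The PBS library was assumed to vary as the pristane pairs did, which holds for every PBS result here. Leaving out any 1 of the 4 pristane libraries left 0 genes past the limma threshold, with 2755 to 3755 genes at an unadjusted p under 0.05.

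After pristane, mature neutrophil genes had the highest median of the lists tested. Among 12 mature neutrophil genes, 8 rose past the threshold over all genes, 11 rose when adjusted over the list alone, and none fell, with a median log2 change of 4.79 (camera adjusted p = 5.5e-08, adjusted p = 0.487 with an estimated correlation). S100a8 and S100a9 encode the subunits of calprotectin, the main cytosolic protein of neutrophils. S100a8 rose from 92.5 FPKM to 10376 and 9877 FPKM (log2 change 6.76 ± 0.47 SE, adjusted p = 0.0247), and S100a9 from 38.7 FPKM to 5295 and 3833 FPKM. Trem1, an activating receptor of neutrophils and monocytes, rose by 4.60 on the log2 scale, and Lcn2, an iron-withholding granule protein, by 6.13. Il1r2, the decoy receptor for interleukin-1, was listed at 0 with PBS and stood at 212 and 321 FPKM after pristane. Stfa2l1, a stefin made by mouse neutrophils, was likewise listed at 0 with PBS against 191 and 207 FPKM. Asprv1, a protease gene, rose by 6.97 on the log2 scale. The 14 genes of neutrophil granules and precursors had a median of 2.02 (adjusted p = 0.00326, adjusted p = 0.622 with an estimated correlation), with 4 higher and 1 lower when adjusted over the list alone. The median was 1.75 in WT pristane replicate 1 and 3.10 in replicate 2 alone.

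Single genes of macrophage activation rose too, while the 10 genes of alternative activation did not pass as a list (median 0.74, adjusted p = 0.145, adjusted p = 0.822 with an estimated correlation). That list's median was −0.03 in WT pristane replicate 1 and 1.27 in replicate 2 alone. Spp1, which encodes the secreted adhesive protein osteopontin, had the largest fold change of the named genes, from 17.6 FPKM to 5509 and 5626 FPKM (log2 change 8.23 ± 0.23 SE, adjusted p = 0.0135). Arg1, the arginase of alternatively activated and suppressive myeloid cells, rose from 58.7 FPKM to 3858 and 8864 FPKM. Irg1, the mitochondrial enzyme that makes itaconate in stimulated macrophages (also called Acod1), rose from 2.59 FPKM to 941 and 195 FPKM. AA467197, listed under its clone name, rose by 7.78 on the log2 scale. Tgm2, a transglutaminase of alternative activation, rose by 5.38. Among 14 genes of lipid uptake and handling 4 rose and 1 fell (median 1.42, adjusted p = 0.00832, adjusted p = 0.487 with an estimated correlation). Those that rose were the lipid-sensing receptor Trem2 (log2 change 4.03), the oxidized lipoprotein receptor Olr1 (4.25), the fatty acid carrier Fabp5 (2.49) and the lysosomal protein Gpnmb (5.80). Interleukin-1 led the cytokines: Il1b rose from 17.7 FPKM to 2118 and 939 FPKM, and its antagonist Il1rn by 5.84 on the log2 scale. The 11 inflammatory cytokines had a median of 0.50, with 5 higher when adjusted over the list alone (adjusted p = 0.00536, adjusted p = 0.487 with an estimated correlation). Their median was 1.38 in WT pristane replicate 1 and 1.03 in replicate 2 alone.

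Markers of inflammatory monocytes, the blood-derived cells named in the study's title, rose after pristane with a median log2 change of 3.15 over 12 genes (adjusted p = 6.5e-04, adjusted p = 0.518 with an estimated correlation). 3 rose past the threshold and 7 when adjusted over the list alone. Ly6c2, which encodes the surface antigen that defines these cells, rose from 2.51 FPKM to 145 and 296 FPKM (log2 change 5.89 ± 0.67 SE, adjusted p = 0.0296). Fcgr1, the high-affinity IgG receptor, rose from 2.59 FPKM to 73.1 and 271 FPKM. Natural killer cell markers had a median of 2.10 over 9 genes (adjusted p = 1.2e-04, adjusted p = 0.487 with an estimated correlation), with 7 higher when adjusted over the list alone. They included the granzymes Gzma (log2 change 4.73) and Gzmb (3.96) and the activating receptor Ncr1 (2.28). T cell markers did not pass as a list (median −0.30, adjusted p = 0.408).

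Of 27 type I interferon response genes, 22 rose past the threshold and 25 when adjusted over the list alone (median 2.96, adjusted p = 5.6e-16, adjusted p = 0.487 with an estimated correlation). Rsad2, which encodes the antiviral enzyme viperin, rose from 1.47 FPKM to 130 and 169 FPKM (log2 change 5.92 ± 0.26 SE, adjusted p = 0.0201). Irf7, the factor that amplifies interferon production, rose by 5.85 on the log2 scale. Ifit1, a sensor of foreign RNA caps, rose by 4.16, and Oas3, a sensor of double-stranded RNA, by 4.40. Zbp1, a nucleic acid sensor of cell death pathways, rose by 2.96. The 11 interferon gamma response genes did not pass as a list (median 0.63, adjusted p = 0.204), and Ifi47, an interferon-induced GTPase, rose by 2.51. The interferon gamma median was 0.21 in WT pristane replicate 1 and 1.06 in replicate 2 alone.

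All 15 genes of glycolysis and the hypoxia response rose when adjusted over the list alone, 11 of them past the threshold over all genes (median 2.37, adjusted p = 1.3e-09, adjusted p = 0.487 with an estimated correlation). Bnip3, a mitochondrial target of hypoxia signalling, rose by 3.71 on the log2 scale, the glycolytic kinase Pgk1 by 2.86 and lactate dehydrogenase Ldha by 2.53. Among 14 matrix proteases and their inhibitors, 12 rose and 1 fell when adjusted over the list alone (median 3.98, adjusted p = 1.0e-05, adjusted p = 0.487 with an estimated correlation). Mmp12, the macrophage elastase, rose by 4.74, the gelatinase Mmp9 by 4.13, the metalloprotease Adam8 by 4.23 and the inhibitor Timp1 by 5.38. 5 genes of coagulation and fibrinolysis rose and 1 fell out of 13 (median 1.09, adjusted p = 0.0367, adjusted p = 0.487 with an estimated correlation). The list's adjusted p was 0.0817 without WT pristane replicate 2 and 0.0502 and 0.0504 without Irf8KO pristane replicates 1 and 2. They included the clotting factors F7 (log2 change 2.11) and F10 (2.14), the plasminogen activator Plau (2.52) and its receptor Plaur (2.10). 3 of 17 Toll-like receptor genes rose past the threshold, among them Tlr2, the receptor for bacterial lipoproteins (3.15), and Myd88, the adaptor shared by most Toll-like receptors (1.82). The list had a median of 0.74 (adjusted p = 0.00925, adjusted p = 0.487 with an estimated correlation), and of 0.46 without WT pristane replicate 2.

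Further lists that passed were those of chemokines (18 genes, median 2.32, adjusted p = 0.00326, adjusted p = 0.487 with an estimated correlation) and NF-kB response genes (12 genes, median 1.41, adjusted p = 0.00227, adjusted p = 0.622 with an estimated correlation). The NF-kB median was 2.02 in WT pristane replicate 1 and 0.90 in replicate 2 alone. NADPH oxidase and nitric oxide genes had a median of 1.23 over 7 genes (adjusted p = 0.0150, adjusted p = 0.487 with an estimated correlation), with the oxidase subunit Ncf4 (1.67) among those past the threshold. Myeloid transcription factors had a median of 0.95 over 18 genes (adjusted p = 0.0107, adjusted p = 0.510 with an estimated correlation). Spi1, the master factor of myeloid cells, rose by 2.07 on the log2 scale, and Irf4, a factor of B cells and some macrophages, fell by 3.12. The 13 complement and Fc receptors had a median of 1.18 (adjusted p = 0.0367, adjusted p = 0.487 with an estimated correlation), with a median of 0.60 and adjusted p = 0.0651 without WT pristane replicate 2 and 0.0504 without Irf8KO pristane replicate 2. The complement C5a receptor C5ar1 was among those that rose (2.76). MHC class I presentation genes had a median of 0.37 over 11 genes (adjusted p = 0.0175, adjusted p = 0.487 with an estimated correlation), with no member past the threshold and an adjusted p of 0.0544 without WT pristane replicate 1. The 5 fibroblast genes passed as a list (adjusted p = 0.00580, adjusted p = 0.544 with an estimated correlation), but all were listed at 0 with PBS, where a 0 may be a failed estimate, so this is not read as a rise. Dcn, a collagen-binding proteoglycan, was listed at 0 with PBS and stood at 19.3 FPKM in both WT pristane libraries.

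Large peritoneal macrophage markers fell after pristane, with a median log2 change of −3.61 over 17 genes (adjusted p = 8.5e-06, adjusted p = 0.510 with an estimated correlation). 11 fell past the threshold and 1 rose, and 14 fell when adjusted over the list alone. Alox15, the lipoxygenase of resident peritoneal macrophages, fell from 1046 FPKM to 1.99 and 9.04 FPKM (log2 change −7.58 ± 0.85 SE, adjusted p = 0.0296). Timd4, a receptor for dying cells (log2 change −3.99), Selp, an adhesion molecule of these cells (−4.79), Ltbp1, which binds latent TGF-beta (−5.60), and Prg4, a lubricating proteoglycan (−6.09), fell too. The member that rose was F10. Cxcl13, the B cell chemoattractant of the peritoneum, had the largest fall of the named genes, from 572 FPKM to 1.26 and 1.49 FPKM (log2 change −7.92 ± 0.31 SE, adjusted p = 0.016).

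B cell markers fell with a median of −5.17, all 11 when adjusted over the list alone and 9 past the threshold over all genes (adjusted p = 3.0e-07, adjusted p = 0.487 with an estimated correlation). The antigen receptor subunits Cd79a (−6.74) and Cd79b (−6.79) and the surface protein Ms4a1, also known as CD20 (−7.30), were among them. Ly6d (−6.11) and Mzb1 (−5.94), genes of B-lineage cells, fell as well. MHC class II genes had a median of −2.27 over 10 genes (adjusted p = 0.00832, adjusted p = 0.680 with an estimated correlation), −1.40 in WT pristane replicate 1 and −3.22 in replicate 2 alone. None passed over all genes, and the invariant chain Cd74 stood at 4799 FPKM with PBS against 1790 and 360 FPKM. Mast cell markers fell in 8 of 9 cases (median −1.70, adjusted p = 7.3e-07, adjusted p = 0.487 with an estimated correlation), with the chymase Cma1 going from 134 FPKM to 1.12 and 0.834 FPKM and the carboxypeptidase Cpa3 falling by 5.60 on the log2 scale. Mcpt4, another chymase of connective tissue mast cells, stood at 70.2 FPKM with PBS and was listed at 0 in all 4 pristane libraries. Ribosomal protein genes fell by a median of 1.47 over 18 genes, all of them when adjusted over the list alone (adjusted p = 1.1e-07, adjusted p = 0.487 with an estimated correlation). Rpl5 (−1.64) and Rps4x (−1.54) were among these.

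Irf8KO pristane against WT pristane asked which parts of the response to pristane differ in the libraries labelled Irf8KO. Type I interferon response genes were far lower in the libraries labelled Irf8KO than in WT pristane. Inflammatory monocyte markers were lower too. Markers of large resident macrophages and of dividing cells were higher. Of the 17 lists that passed by camera, 3 also passed by fry, those of the type I interferon response, MHC class I presentation and the cell cycle, and the other 14 had a fry adjusted p from 0.108 to 0.593. 3 genes passed the threshold over all genes, all of them interferon response genes that fell, and 2293 genes had an unadjusted p under 0.05, where 556 were expected by chance. The count turned on the processing: it was 242 (105 higher, 137 lower) when the filter was a mean of at least 5 FPKM, 431 when the fit held the 4 pristane libraries alone, and 0 by limma when any 1 of those 4 libraries was left out, with 1005 to 2529 genes at an unadjusted p under 0.05. At an adjusted p under 0.1 the counts were 131 genes higher and 159 lower.

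The 3 genes past the threshold were Rsad2, Rtp4 and Ifit1. Rsad2 fell from 130 and 169 FPKM in WT pristane to 1.48 and 1.33 FPKM (log2 change −5.96 ± 0.21 SE, adjusted p = 0.0368). Rtp4, an interferon-induced chaperone, fell from 129 and 135 FPKM to 4.70 and 5.32 FPKM (−4.47 ± 0.16 SE). Ifit1 fell from 50.1 and 49.8 FPKM to 0.153 and 0.221 FPKM (−5.42 ± 0.19 SE), against 1.86 FPKM in the PBS library. Of the 27 type I interferon response genes, 26 fell and none rose when adjusted over the list alone (median −3.46, adjusted p = 2.3e-27, adjusted p = 0.460 with an estimated correlation, fry adjusted p = 0.0112). Irf7 stood at 393 and 482 FPKM in WT pristane against 11.4 and 15.7 FPKM, and Zbp1 at 249 and 260 FPKM against 21.3 and 16.9 FPKM. Bst2, the membrane tether that holds back enveloped viruses, had a log2 change of −2.20. Without WT pristane replicate 2, which left only libraries with Y-linked transcripts on both sides, the list's median was −3.21.

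**Figure D1:**
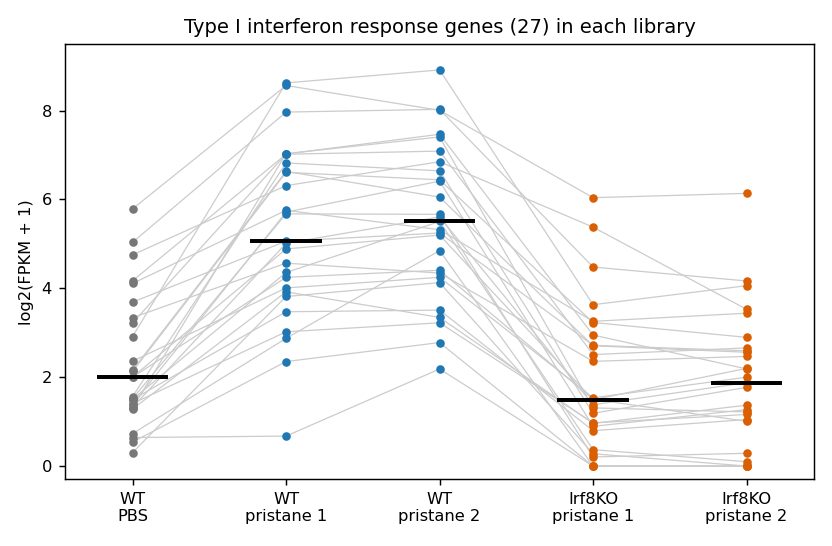
The log2(FPKM + 1) of each of the 27 type I interferon response genes is plotted for the 5 libraries, with grey lines joining the same gene and black bars for the median of each library. Relative to the PBS library, the genes' median difference was 2.85 and 2.99 in the WT pristane libraries and −0.50 and −0.45 in the libraries labelled Irf8KO.

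Genes of the interferon gamma response fell as well, 10 of 11 when adjusted over the list alone (median −1.56, adjusted p = 1.3e-07, adjusted p = 0.675 with an estimated correlation). They included the immunity-related GTPases Ifi47 (log2 change −3.45), Irgm1 (−3.50) and Igtp (−2.32) and the guanylate-binding protein Gbp5 (−2.01), which defend against intracellular microbes. MHC class I presentation genes fell in 8 of 11 cases when adjusted over the list alone (median −0.89, adjusted p = 1.3e-07, adjusted p = 0.460 with an estimated correlation). Tap1, the peptide transporter, had a log2 change of −2.84, Nlrc5, the transactivator of the class I genes, −2.47, and Psmb8, a subunit of the immunoproteasome, −1.68. MHC class II genes had a median of −1.24 over 10 genes (adjusted p = 0.0478, adjusted p = 0.709 with an estimated correlation) and no member that passed. Their call ended without WT pristane replicate 1 (median −0.39, adjusted p = 0.595) and without Irf8KO pristane replicate 2 (−0.90, adjusted p = 0.231), and without WT pristane replicate 2 the median was −2.03.

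Inflammatory monocyte markers fell in 7 of 12 cases and rose in 1 when adjusted over the list alone, with none past the threshold over all genes (median −2.81, adjusted p = 7.7e-04, adjusted p = 0.675 with an estimated correlation, fry adjusted p = 0.191). Without WT pristane replicate 2 the median was −1.93. Ms4a4c, a membrane protein of Ly6C-high monocytes, went from 66.1 and 191 FPKM to 0.254 and 0.548 FPKM (log2 change −6.35 ± 0.57 SE, adjusted p = 0.0562). Ccr2, the receptor that brings monocytes out of the bone marrow, went from 27.1 and 85.5 FPKM to 5.03 and 3.13 FPKM, and Fcgr1 from 73.1 and 271 FPKM to 2.97 and 3.72 FPKM. Plac8, abundant in monocytes and other leukocytes, went from 640 and 863 FPKM to 109 and 57.1 FPKM. Csf1r, the macrophage colony-stimulating factor receptor, did not pass by either adjustment (log2 change 0.63). Ccl2, the ligand of Ccr2, stood at 247 and 2519 FPKM in WT pristane against 36.0 and 28.6 FPKM and did not pass either (adjusted p = 0.172). The first complement component's subunit C1qa, made by macrophages, went from 383 and 287 FPKM to 19.8 and 41.8 FPKM and passed when adjusted over its list alone, in which 4 of 11 genes rose and 4 fell.

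Conventional dendritic cell markers fell in 5 of 10 cases when adjusted over the list alone (median −0.80, adjusted p = 2.5e-04, adjusted p = 0.675 with an estimated correlation). Batf3, the factor required by cross-presenting dendritic cells, stood at 4.98 and 4.12 FPKM in WT pristane against 0.469 FPKM and a listing of 0, and Flt3, the growth factor receptor of dendritic cells, at 4.43 and 1.86 FPKM against 0.053 and 0.153 FPKM. Small peritoneal and monocyte-derived macrophage markers had a median of −1.73 over 8 genes, none of which passed on its own (adjusted p = 0.0190, adjusted p = 0.675 with an estimated correlation), and of −0.75 without WT pristane replicate 2. Natural killer cell markers fell in 5 of 9 cases (median −1.24, adjusted p = 4.2e-05) and T cell markers in 5 of 14 (median −1.04, adjusted p = 1.2e-05) when adjusted over each list alone. Both lists had an adjusted p = 0.675 with an estimated correlation. Gzmb had a log2 change of −2.71 and the killer cell receptor Klrk1 of −1.74. Cd8b1, a chain of the cytotoxic T cell coreceptor, changed by −2.64 and Cd3e, a signalling chain of the T cell receptor, by −1.08. Among Toll-like receptor genes (17 genes, median −0.73, adjusted p = 1.9e-04, adjusted p = 0.675 with an estimated correlation), Tlr9, the endosomal DNA sensor, had a log2 change of −1.87. Lipid uptake genes had a median of −0.77 over 14 genes (adjusted p = 0.00606, adjusted p = 0.675 with an estimated correlation), of which the scavenger receptor Cd36 alone passed over its list (−2.97).

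Large peritoneal macrophage markers rose in 13 of 17 cases and fell in none when adjusted over the list alone (median 2.77, adjusted p = 5.3e-10, adjusted p = 0.675 with an estimated correlation, fry adjusted p = 0.108). Selp went from 1.34 and 2.08 FPKM in WT pristane to 69.0 and 136 FPKM (log2 change 5.19 ± 0.40 SE, adjusted p = 0.0542). Icam2, an adhesion molecule used to sort these cells, went from 27.3 and 13.4 FPKM to 357 and 402 FPKM, and the clotting factor F5 had a log2 change of 4.44. Gata6, the factor that sets the identity of resident peritoneal macrophages, went from 1.96 and 1.40 FPKM to 7.70 and 15.7 FPKM, against 6.13 FPKM in the PBS library, and passed over the list alone. Emr1, which encodes the macrophage antigen F4/80, had a log2 change of 2.25. Cxcl13 went from 1.26 and 1.49 FPKM to 32.6 and 48.2 FPKM. Serpinb2, an inhibitor of plasminogen activation, had a log2 change of 4.10, and Plau, which activates plasminogen, of −3.64. Without WT pristane replicate 2 the median of the macrophage list was 3.76. B cell markers had a median of 1.68 over 11 genes, 4 of them higher when adjusted over the list alone (adjusted p = 0.00142, adjusted p = 0.675 with an estimated correlation). They included Cd79b (2.68). The B cell median was 0.77 without WT pristane replicate 2 and 0.73 without Irf8KO pristane replicate 1.

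**Figure D2:**
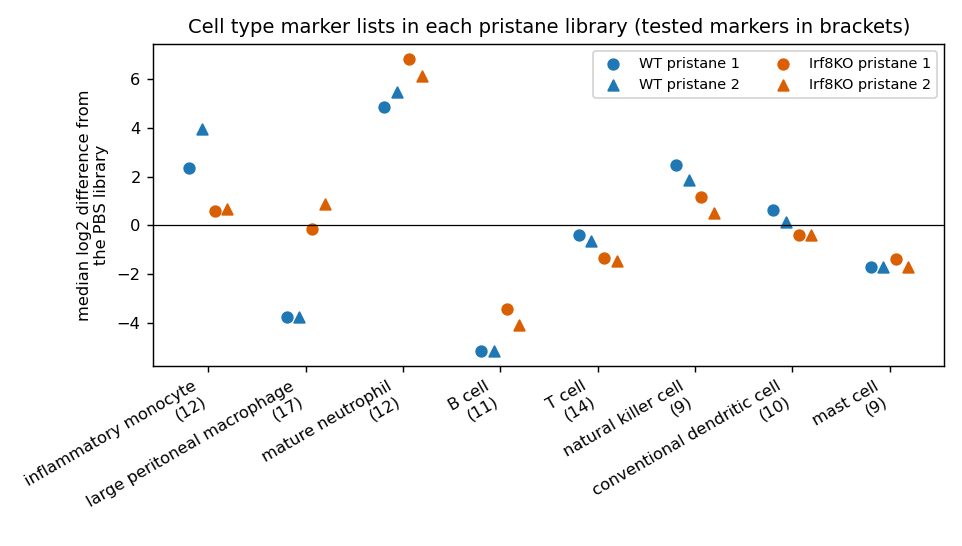
Each point is the median log2 difference from the PBS library over the tested markers of a cell type, on the log2(FPKM + 1) scale, in 1 of the 4 pristane libraries. Large peritoneal macrophage markers lay at −3.78 and −3.76 in the WT libraries and at −0.15 and 0.89 in the libraries labelled Irf8KO, and inflammatory monocyte markers at 2.37 and 3.94 against 0.59 and 0.66.

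Cell cycle genes rose in 17 of 18 cases when adjusted over the list alone (median 1.94, adjusted p = 6.6e-14, adjusted p = 0.460 with an estimated correlation, fry adjusted p = 0.0206). The mitotic cyclin Ccnb2 went from 1.03 and 0.768 FPKM in WT pristane to 14.9 and 15.1 FPKM, and Ccnb1 had a log2 change of 2.88. Birc5, which encodes the mitotic protein survivin, had a log2 change of 2.54 and Ube2c, a ubiquitin-conjugating enzyme of mitosis, of 2.82. Genes of neutrophil granules and precursors had a median of 1.20 over 14 genes (adjusted p = 0.0120, adjusted p = 0.675 with an estimated correlation). That call ended without WT pristane replicate 1 (median 0.71, adjusted p = 0.205) and without Irf8KO pristane replicate 1 (1.01, adjusted p = 0.179), and the median was 2.05 without WT pristane replicate 2. The granule protease Prtn3 (log2 change 3.84) and the antimicrobial peptide Camp, at 6.33 and 10.6 FPKM in WT pristane against 287 and 116 FPKM, were its 2 members past the threshold over the list alone. Mature neutrophil genes did not pass as a list (median 0.92, adjusted p = 0.060), and S100a8 stood at 29441 and 16300 FPKM in the libraries labelled Irf8KO. Saa3, an acute phase protein of macrophages chosen after its values were seen, had the highest FPKM of both these libraries, at 40842 and 36484 FPKM against 1337 and 628 FPKM in WT pristane. Il6, the cytokine that drives the acute phase, went from 26.0 and 26.3 FPKM to 101 and 76.7 FPKM and passed when adjusted over its list alone.

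Among 18 myeloid transcription factors, 1 rose and 6 fell when adjusted over the list alone (median −0.63, adjusted p = 0.0387, adjusted p = 0.675 with an estimated correlation). The call ended without WT pristane replicate 1 (median −0.41, adjusted p = 0.168) and without Irf8KO pristane replicate 2 (−0.53, adjusted p = 0.0739). Pparg, the lipid-sensing nuclear receptor of macrophages, stood at 5.86 and 5.88 FPKM in WT pristane against 0.926 and 0.530 FPKM, and was listed at 0 with PBS. Ribosomal protein genes had a median of 0.22 over 18 genes (adjusted p = 0.0152, adjusted p = 0.675 with an estimated correlation), with none past the threshold. Scaling by library totals turned that median to −0.01, and the call also ended without WT pristane replicate 1 (adjusted p = 0.138), WT pristane replicate 2 (0.0504) or Irf8KO pristane replicate 1 (0.244, median 0.10). Without Irf8KO pristane replicate 2 the median was 0.46. Genes listed as targets of Irf8 did not pass as a list (11 genes, median −0.07, adjusted p = 0.516).

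**Figure D3:**
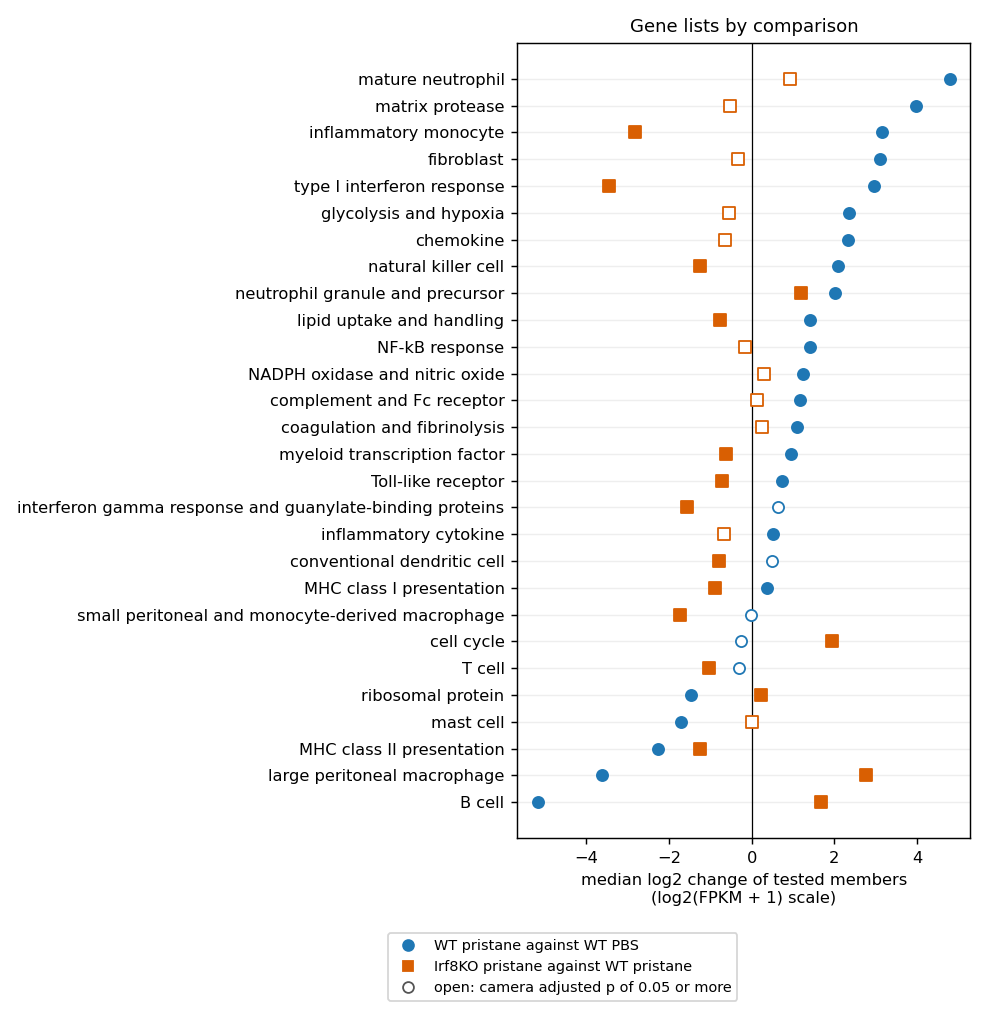
The median log2 change of each gene list is plotted for WT pristane against WT PBS (circles) and Irf8KO pristane against WT pristane (squares), with open symbols for lists whose camera adjusted p was 0.05 or more. The type I interferon list lay at 2.96 and −3.46, and the large peritoneal macrophage list at −3.61 and 2.77.

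Irf8KO pristane against WT PBS differed in both genotype and treatment, so it belongs to neither alone. It also coincided with the split in transcripts that mark sex. Xist stood at 43.5 FPKM in the PBS library against 0.0148 and 0.0145 FPKM in the libraries labelled Irf8KO. Eif2s3y was listed at 0 in the PBS library against 23.2 and 25.6 FPKM. 949 genes passed, 424 higher and 525 lower, against the 1 PBS library; leaving out any 1 pristane library left 0 by limma, with 2242 to 4013 genes at an unadjusted p under 0.05. Neutrophil genes were higher (median 6.52, adjusted p = 1.4e-08) and B cell (median −3.98, adjusted p = 4.3e-06) and mast cell markers (−1.54, adjusted p = 3.5e-07) lower, as in WT pristane. These 3 lists had an adjusted p = 0.623 with an estimated correlation. The type I interferon list (median −0.54, adjusted p = 0.118) and the large peritoneal macrophage list (0.28, adjusted p = 0.969) did not pass. The macrophage list was mixed: 10 members had positive and 7 negative log2 changes, from −4.42 to 2.39. Its median therefore does not mean that each marker stood at the PBS level. Of the genes called in WT pristane, 267 were also called higher and 393 also called lower in Irf8KO pristane, against 22 and 29 for independent lists. Both comparisons used the same PBS library, which cannot be split. Unchanged groups simulated with that shared library gave a covariance of the log2 changes across genes of 0.104, where 1.07 was observed. The simulated PBS library varied only as the pristane libraries did. A PBS library unusual in itself would also raise the observed covariance and the shared calls, so these values cannot tell it from a shared response.

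The genes that pristane changed in WT were then followed into the libraries labelled Irf8KO. The 3 genes that fell there, Rsad2, Rtp4 and Ifit1, had all risen with pristane. Independent lists would give 0.155 such genes. Of the 576 genes that rose with pristane, 458 had a lower value in the libraries labelled Irf8KO, 169 of them by over 2-fold, with a median log2 change of −0.52. Of the 607 that fell, 365 had a higher value, 76 by over 2-fold, with a median of 0.10. Sharing the WT pristane libraries gives some movement back by itself. Across all genes the log2 changes of both comparisons correlated at −0.38, and at −0.41 in the simulated groups. A correlation takes no account of the size of the changes, so it cannot tell sharing from further movement back. The covariance was −0.352, and −0.0521 in the simulated groups, with −0.0667 to −0.0450 over the 100 draws. The share of all genes with opposite directions in both comparisons was 60.5%, and 63.4% in the simulated groups (62.3% to 64.8%). Opposite movement was thus no more frequent than sharing alone gave. Only the covariance, to which large changes add most, went beyond the simulation, so it does not tell how many genes moved back.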

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

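The tests restricted to genes above 0 in every library, those with no variance trend, and the list tests scaled by library totals and upper quartile were chosen after the data were seen; the others were planned. All 48 genes named for Irf8KO against WT pristane and all 64 named for WT pristane against PBS kept the direction of their log2 change under every alternative that tested them, as did the 17 and 23 lists in their camera direction. Irf8 ranged from 0.37 to 0.63 over the scalings and from 0.09 to 1.10 when 1 pristane library was left out, and never fell. Scaling by library totals moved the median log2 change of all genes by −0.17 for Irf8KO against WT pristane. For Irf8KO pristane against PBS it became −0.24 in place of −0.05. All other shifts for Irf8KO against WT pristane and WT pristane against PBS were under 0.1. Camera's direction and the sign of the median differed for complement and Fc receptors (median 0.12) and immediate early genes (0.03) in Irf8KO against WT pristane and for basophil markers (0.20) in WT pristane against PBS, none of them past the threshold.

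The number of genes past the threshold for Irf8KO against WT pristane was the least stable result. In place of 3 it was 48 with median-of-ratios scaling, 242 with a mean of at least 5 FPKM (5894 genes tested), 264 with a robust prior, 431 with the 4 pristane libraries alone, 500 with genes above 0 in every library, 40 with no variance trend and 5 with a pseudocount of 5. It was 0 with library totals scaling, no filter, a pseudocount of 0.1 or a test against a log2 change of 1, while limma gave 2424, 2586, 2234 and 385 genes at an unadjusted p under 0.05. The 3 called genes were among the 242 and the 500. For each of these shifts the cause was not tested, except that a test against a log2 change of 1 asks for a larger effect.

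The replicate block, a fit with the replicate number as a term over the 4 pristane libraries, gave 799 genes (384 higher, 415 lower) and 22 lists. It also left out the PBS library, which alone gave 431 genes. Deviations of same-numbered libraries correlated at 0.045 across genes, so the numbers did not pair libraries and the block is not an estimate to prefer.

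WT pristane against PBS gave 846 to 1707 genes under the alternatives that kept all libraries and 34 when tested against a log2 change of 1. The share that was higher ran from 29.2% with no filter to 68.7% with a mean of at least 5 FPKM. Irf8KO pristane against PBS gave 13 genes against a log2 change of 1, 1505 among genes above 0 in every library and 623 with no variance trend, in place of 949, and 933 to 1272 or 641 (pseudocount 0.1) otherwise. Pristane genes moved back past the threshold numbered 3 at first, 34 with median-of-ratios scaling, 140 with a mean of at least 5 FPKM, 141 with a robust prior, 218 among genes above 0 in every library, 27 with no variance trend and 5 with a pseudocount of 5. They numbered 0 with library totals scaling, no filter, a pseudocount of 0.1 and a test against a log2 change of 1. The cause was not tested for these either.

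Leaving out any 1 pristane library (WT pristane replicate 1 or 2, Irf8KO pristane replicate 1 or 2) left 0 genes past the limma threshold in all 3 comparisons and 0 moved back, with 1 residual degree of freedom in place of 2. List counts then stayed at 15 to 20 for Irf8KO against WT pristane and 21 to 24 for WT pristane against PBS. With an estimated correlation 0 lists passed in both. Fry called 3 and 9 lists.

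Some list calls ended with all libraries kept. For Irf8KO against WT pristane these were, with library totals scaling, small peritoneal macrophages (adjusted p = 0.0664), MHC class II (0.109), myeloid transcription factors (0.0683) and ribosomal proteins (0.113, median −0.01); MHC class II with a pseudocount of 0.1 (0.0573) and no filter (0.0608); and myeloid transcription factors with a pseudocount of 0.1 (0.0563), a mean of at least 5 FPKM (0.148) and genes above 0 in every library (0.144). For WT pristane against PBS, a mean of at least 5 FPKM ended the calls of neutrophil granules (0.0519), MHC class I, Toll-like receptors and coagulation (each 0.189), NADPH oxidase (0.0602), lipid uptake (0.0503) and myeloid transcription factors (0.111). Coagulation also ended with median-of-ratios scaling (0.0519) and a pseudocount of 0.1 (0.0510). The cause was not tested.

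Depth limits the rare transcripts: with 1 fragment worth up to 0.438 FPKM on a transcript of 1 kb, values of a few FPKM, as for most dendritic cell markers, rest on few fragments.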

Other observations

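All tests in this part were chosen after the results were seen, as were the genes named outside the naming rule. Gene families formed by symbol, 12 in all, gave patterns outside the fixed lists, and each family direction given here held under the 3 scalings and without each pristane library. After pristane in WT mice, the Gimap GTPases, survival factors of lymphocytes, fell in 6 of 8 cases past the threshold (median log2 change −2.17, camera adjusted p = 4.2e-05, adjusted p = 0.424 with an estimated correlation). Subunits of the vacuolar ATPase, the proton pump of lysosomes, rose in 7 of 16 cases (median 1.38, adjusted p = 9.4e-06, adjusted p = 0.424 with an estimated correlation). Cytosolic ribosomal proteins fell in 37 of 77 cases (median −1.54, adjusted p = 6.6e-20, adjusted p = 0.459 with an estimated correlation). All of these rest on the 1 PBS library.

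Between the pristane groups, the 6 Schlafen genes, interferon-induced regulators of growth and translation, all had negative log2 changes in the libraries labelled Irf8KO (median −2.04, adjusted p = 4.6e-05, adjusted p = 0.247 with an estimated correlation). The replication licensing genes of the Mcm, Gins and Orc families had positive changes in 15 of 16 cases (median 0.82, adjusted p = 4.4e-05, adjusted p = 0.247 with an estimated correlation). Ribosomal protein genes had positive changes in 75 of 77 cases (median 0.52, adjusted p = 4.9e-10, adjusted p = 0.391 with an estimated correlation), with a median of 0.29 under library totals scaling and 0.33 without Irf8KO pristane replicate 1. Complex I subunits of mitochondria had positive changes in 31 of 36 (median 0.35, adjusted p = 1.0e-05, adjusted p = 0.335 with an estimated correlation), with a median of 0.12 under library totals scaling. No member of these 4 families passed the threshold on its own.

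The WT pristane libraries differed from each other more than those labelled Irf8KO did, with 147 against 36 of 11117 genes apart by over 4-fold. Several of the widest gaps were monocyte chemokines: Ccl2 stood at 247 FPKM in replicate 1 and 2519 FPKM in replicate 2, Ccl7 at 50.3 and 898 FPKM and Ccl12 at 17.6 and 284 FPKM. Members of the neutrophil lists were among the wide gaps too. Ngp stood at 15.3 and 153 FPKM, Ltf at 4.82 and 42.6 FPKM and Mmp8 at 21.7 and 128 FPKM, while G0s2 was lower in replicate 2, at 385 and 65.8 FPKM. Chil3, a chitinase-like protein of alternatively activated macrophages and neutrophils, stood at 88.9 and 4000 FPKM. The fractalkine receptor Cx3cr1 went the other way, at 89.3 and 5.68 FPKM, as did the scavenger receptor Marco, at 18.7 and 0.934 FPKM. Rn45s, the ribosomal RNA precursor, was listed at 14587 FPKM in replicate 1 and at 0 in replicate 2. It was also listed at 0 in the PBS library and stood at 9001 and 10403 FPKM in the libraries labelled Irf8KO. Rn45s thus grouped the libraries as Xist and Eif2s3y did, with the PBS library beside WT pristane replicate 2. This grouping splits the WT pristane libraries, and it coincides with the comparison of Irf8KO pristane with WT PBS. No reason for these gaps was tested, and the same libraries differ in Xist and Y-linked transcripts.

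Irf8KO pristane replicate 1 held low levels of transcripts made by liver cells. Alb, which encodes albumin, stood at 25.6 FPKM there, at 0.446 FPKM in Irf8KO pristane replicate 2 and was listed at 0 in the other 3 libraries. Apoa1 stood at 21.4 FPKM, Hpx at 10.3 FPKM, Mup20 at 8.34 FPKM and Serpina3k at 8.29 FPKM in replicate 1. No test of their origin was made.

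The fall of type I interferon response genes in the libraries labelled Irf8KO was weighed against 3 explanations. Scaling of the libraries is argued against: over the 3 scalings the list median nearest 0 was −3.44. WT pristane replicate 2, which alone among the pristane libraries expresses Xist, is argued against as the whole cause: without it the median was −3.21. A lower share of inflammatory monocytes, with the interferon genes of each cell unchanged, stays open. The upper quartile of the interferon genes was −2.41 and the lower quartile of the monocyte markers −3.31, so the ranges overlap. This takes the monocyte markers to follow the number of monocytes. If some of them respond to interferon themselves, the overlap says nothing about the number of cells, and this was not tested. A direct effect of the genotype on the interferon response and a loss of the cells that carry it cannot be told apart, because the libraries hold mixed cells.

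Large peritoneal macrophage markers, higher in the libraries labelled Irf8KO, were weighed in the same way. The lowest list median over the 3 scalings was 2.56, and without WT pristane replicate 2 it was 3.76, which argues against both as the whole cause. A lower share of monocytes would raise the markers of every other cell type alike. The upper quartile of T cell markers was −0.84 and the lower quartile of the macrophage markers 2.03. Other lists lay on both sides of 0, with medians of 1.68 for B cells, 1.20 for neutrophil granules, 0.92 for mature neutrophils and −1.24 for natural killer cells. A lower share of monocytes is thus argued against as the whole cause, as far as T cells did not fall for a reason of their own. It stays open as a part of the rise. No other biological explanation was tested. Timd4, chosen after its values were seen, was the list's 1 member with a negative log2 change (−0.43): it stood at 26.9 FPKM with PBS, 0.676 and 0.838 FPKM in WT pristane and 0.0957 and 0.552 FPKM in the libraries labelled Irf8KO.

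Irf8 RNA that was not lower in the libraries labelled Irf8KO was the last pattern weighed. A library scaling that hides a 2-fold or larger fall is argued against, since the lowest end of the 95% interval over the 3 scalings was −0.58. A single pristane library with the label of the other pristane group is argued against too: the highest correlation across genes between libraries of different labels was 0.933, and the lowest between libraries of the same label 0.952. An exchange of the labels of both pristane groups is argued against as far as Irf8 loss lowers inflammatory monocytes, which is taken from prior knowledge and not from these libraries. It also assumes that the monocyte markers follow the number of these cells and not the interferon response, which was not tested. An exchange would then put monocyte markers higher in the libraries labelled Irf8KO. Their upper quartile was −1.86 there, and the highest it reached without any 1 pristane library was −1.19. This test followed one on dendritic cell markers, which also depend on Irf8: their median was −0.80, but only 2 members reached a mean of 5 FPKM, so it decided nothing. An allele whose RNA is still made without working protein may give these values and stays open. It was not tested, because FPKM per gene does not show exons.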
